A study of Streptomyces clavuligerus with 12 samples.

How the data were processed

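Total RNA of the wild type of Streptomyces clavuligerus and of its claR mutant (ΔclaR::aac, in which aac, a resistance gene, was put in place of claR) was measured on 12 Agilent arrays with 2 colours each. Cultures in starch-asparagine medium were sampled at 22.5, 46.5 and 60 h, with 2 biological replicates per strain and time per the labels. The RNA was stabilised with RNAprotect, copied into cDNA from random primers with SuperScript II and labelled with Cy3. Genomic DNA of the wild type from a stationary culture was labelled with Cy5 and served as the reference on every array, so no array measured DNA of the mutant.

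The deposited scanner files hold the intensity of each spot in both colours, and per the file headers they were made by Agilent Feature Extraction 9.5.1.1 with a CGH protocol. Per the file headers the mean, median and background signals are unnormalised intensity, and the processed signals are intensity after background subtraction, detrending and dye normalization. The deposited log ratio column of these files is a log10 value of Cy5 over Cy3, the opposite direction to expression, and it was not used. The deposited spot flags (well above background, saturated, non-uniform, population outlier) are in no physical unit, only 0 or 1, and count as other values per the file headers. The authors' series matrix holds 1 value per spot group, and by comparison with the scanner files the deposited values are on the log2 scale of Cy3 over Cy5. Over the 12 arrays they correlated with the log2 ratio of the processed signals with r of 0.982 to 0.991 across spots, and their medians lay between 0.114 and 0.294. The authors name limma without a version. Their normalization method and centring are not given in the sources used here, and these values served only as an alternative.

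For each spot the mean signal was corrected with the normexp method of limma 3.58.1 in R 4.3.3, with an offset of 50 and the median local background. Spots flagged in either colour as non-uniform or as population outliers were set to missing. The log2 ratio of Cy3 to Cy5 rises with expression. It was averaged over spots to probes and over probes to genes, and centred on the array's median over genes. No intensity-dependent loess was applied in the setting reported, because the ratio to genomic DNA correlated with mean brightness on every array (r from 0.357 to 0.544 across spots), and a loess would remove such a trend whether it comes from expression or dye. A probe was kept where Cy5 was well above background on 10 or more arrays and Cy3 on both arrays of at least 1 group. Of 15208 non-control spots, 14908 distinct probes remained after merging repeats, 11659 of them named after a gene and 3249 not. The unnamed probes lay antisense to a gene (2387), between genes (849) or along a gene (13), and they entered no comparison of genes. Of 7535 genes on the array 7533 were tested, 5924 on the chromosome and 1609 on the megaplasmid pSCL4. There were 251 missing gene values, 6 genes had a group that was not well above background, and 441 genes had a probe that the design lists as cross-hybridising.

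Arrays have no sequencing depth, so their number limits the precision. The median Cy3 signal was 303 to 545 intensity units per array and the median Cy5 signal 1757 to 4656. Cy3 was well above background for 99.5% to 99.9% of spots.

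The 6 groups were fitted as 6 means over 12 arrays with lmFit and eBayes of limma, with 6 residual degrees of freedom, 4.38 prior degrees of freedom and a prior SD of 0.223. The contrasts were the mutant minus the wild type at each time and averaged over the 3 times, each time step within each strain, and an F test of the strain by time interaction. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Errors printed as ± are the standard errors of limma's contrasts, with 2 arrays per group. They rest on a spread pooled over all 6 groups and do not show the spread of the groups compared. These tests, the lists, the alternatives and the rule for naming genes were chosen before the data were examined, except where stated. Genes are named by this rule. In each strain contrast claR comes first, then up to 10 of the highest and 10 of the lowest log2 fold changes among changed genes for which both mutant arrays lay on the same side of both wild-type arrays. From each list that passed its test or held 3 or more changed members up to 4 members are named, largest change first. Any gene of the clavulanic acid, cephamycin C and clavam lists may be named. Time contrasts use 5 in place of 10, and the interaction uses the 10 smallest adjusted p. The result of 1 gene that this rule selects is not reported here.

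Gene lists were tested with camera of limma at a preset correlation of 0.01 and again with a correlation estimated per list, over the 25 of 26 lists with 5 or more measured genes and 7312 genes. The files hold no product names, so lists defined by product were rebuilt from gene symbols before any value was tested, and the sta, moe and 3 tiled-block lists were added then from names and probe density on the array. The holomycin list is a range of locus tags that equals a densely tiled block, and its annotation could not be checked. Planned lists for tunicamycin, naringenin, other polyketides and nonribosomal peptides, beta-lactamases and penicillin-binding proteins, sigma factors, iron and mobile elements were dropped for lack of product names. Coordinates are those of the array design, whose genome build is not given in the sources used here.

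The 12 arrays lay on 5 slides with 3 scan dates, and no slide held both strains. Slide was fitted as a random block for strain contrasts (estimated correlation 0.247) and as a fixed block for time contrasts (3 residual degrees of freedom). Other alternatives were within-array loess, Cy3 alone with quantile normalization, Agilent's processed signals, the series matrix, no filter, the median over probes, replicate number as a block, only the 2 groups compared, and leaving out each array in turn. Added after the data were seen were centring on all non-control probes, leaving out the genes at the end of pSCL4, scan date as a block, the average without the 60 h arrays, and list tests with slide as a block.

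The fit was tested on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale. At 22.5 h it recovered 50 and 89 of them with 10 false calls among 149. The average over times recovered 90 and 98 with 14 false among 202, and the interaction test 8 and 65 with 1 false among 74. Simulated data with no change gave 0 calls in limma. In the simulated list test the shifted list was called and 0 of 15 unshifted lists were. Genes and arrays varied independently in all these simulations, with no slide effect. They therefore do not show how the gene and list tests behave where genes or slides are correlated.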

Results

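Expression was measured on 12 arrays, 2 for each of 6 groups: the wild type and the claR mutant of Streptomyces clavuligerus at 22.5, 46.5 and 60 h of culture. This soil bacterium makes clavulanic acid, an inhibitor of beta-lactamases, and cephamycin C, a beta-lactam antibiotic. The gene claR encodes a LysR-type regulator of the late clavulanic acid genes. The study set out to compare transcription in the wild type with that in a mutant altered in antibiotic production. Values were log2 ratios of Cy3 cDNA to Cy5 genomic DNA for 7533 genes, centred per array. The median signal per array was 303 to 545 intensity units in Cy3 and 1757 to 4656 in Cy5. The 2 arrays of a group correlated across genes with r of 0.98, 0.992 and 0.955 in the wild type at 22.5, 46.5 and 60 h, and of 0.989, 0.989 and 0.98 in the mutant. Genes are not independent replicates, so these r describe the arrays only. All wild-type arrays lay on other slides and were scanned on other dates than all mutant arrays, so strain could not be compared within a slide.

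At 22.5 h the late clavulanic acid genes were far lower in the mutant and the holomycin genes, which make a dithiolopyrrolone antibiotic, were far higher. The target claR itself, at 4852445 to 4853665 on the chromosome of the array design, was lower by a log2 fold change of -4.50 ± 0.19 (adjusted p 1.1e-07), with group means of -0.98 in the mutant and 3.53 in the wild type. Of 10 late clavulanic acid genes 9 were lower (9 adjusted over the list alone), led by fd, a ferredoxin gene, at -5.48 ± 0.19. SCLAV_4189 followed at -5.40 ± 0.21, oppA2, an oligopeptide-binding protein gene, at -4.92 ± 0.17, and gcas, for an enzyme that joins glycine to clavaminic acid, at -4.85 ± 0.18. The exception, SCLAV_4184, had a log2 fold change of -0.01. All 12 holomycin genes were higher (12 adjusted over the list alone), with a median of 6.98 and the highest values in SCLAV_5272 at 7.91 ± 0.17, SCLAV_5271 at 7.81 ± 0.20 and SCLAV_5273 at 7.77 ± 0.19. Camera in limma called both lists shifted (adjusted p 5.6e-24 and 6.5e-33), and both calls held with an estimated correlation (adjusted p = 0.027 for each).

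The other antibiotic genes moved less at 22.5 h. Of the 6 genes in the early clavulanic acid list only oppA1, for an oligopeptide-binding protein, was lower in the test (-4.12 ± 0.28, 1 adjusted over the list alone). That list had a median of 0.20 but a mean of -0.58, and it was not shifted (adjusted p 0.47, and 0.93 with an estimated correlation). In the cephamycin C cluster 3 of 17 genes were higher, here and adjusted over the list alone: blp at 1.55 ± 0.29, SCLAV_4209 at 1.34 ± 0.25 and the activator gene ccaR at 0.79 ± 0.18, which was -0.26 with loess. Its list was called higher (median 0.70, adjusted p 0.00017, 0.54 with an estimated correlation), but with loess its median was -0.09. SCLAV_p1071 of the clavam paralogue cluster on pSCL4 was higher at 2.11 ± 0.25, as 1 of 3 higher genes among 15. Of 25 aerial mycelium and spore genes 4 were lower and 1 was higher. The thioredoxin gene trxA at 2.25 ± 0.40 and the thioredoxin reductase gene trxB at 2.11 ± 0.25 led the 3 higher genes of 20 stress proteins, but with loess both had fold changes at or below 0, -0.02 and -0.23. The tiled block SCLAV_2456 to SCLAV_2469 had 5 of 14 genes lower (9 adjusted over the list alone), SCLAV_2463 first at -1.25 ± 0.22, and its list passed (adjusted p 0.00023, 0.53 with an estimated correlation). The tiled block SCLAV_4387 to SCLAV_4392 had 3 of 6 lower (4 adjusted over the list alone), SCLAV_4387 first at -1.60 ± 0.33 (adjusted p of the list 0.00078, 0.53 with an estimated correlation). The moe list, of 17 genes named like a moenomycin cluster, passed as lower with 0 genes past the test in limma (median -0.30, adjusted p 0.0023, 0.53 with an estimated correlation). No ribosomal protein gene was lower and 1 of 40 was higher, with a list median of 0.04 that turned to -0.35 with loess and to -0.73 with Cy3 alone, where the list was called lower.

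Over all genes, limma called 652 of 7533 changed at 22.5 h, 366 higher and 286 lower, of which 203 and 202 differed 2-fold or more. On pSCL4 226 genes changed, 166 of them lower, and the lowest of all were SCLAV_p1381 at -6.74 ± 0.21 and SCLAV_p1415 at -6.46 ± 0.54. Both lie in the last 305.7 kb of that megaplasmid, where 117 of 269 genes were lower and 1 was higher at this time. The pSCL4 list was called lower (adjusted p 0.0016, 0.72 with an estimated correlation), and without that end its unadjusted camera p was 0.191. The count was 377 or 344 without either 22.5 h array of the wild type, 321 or 325 without either of the mutant, and 1018 without either 60 h array of the wild type. Leaving out 1 of the 22.5 h arrays ended the calls of blp, SCLAV_4209, ccaR, SCLAV_4387 or trxA, and loess ended those of blp, SCLAV_2463 and SCLAV_4387. With Cy3 alone 255 genes were higher and 462 lower, and with loess 145 were higher and 350 lower.

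**Figure D1:**
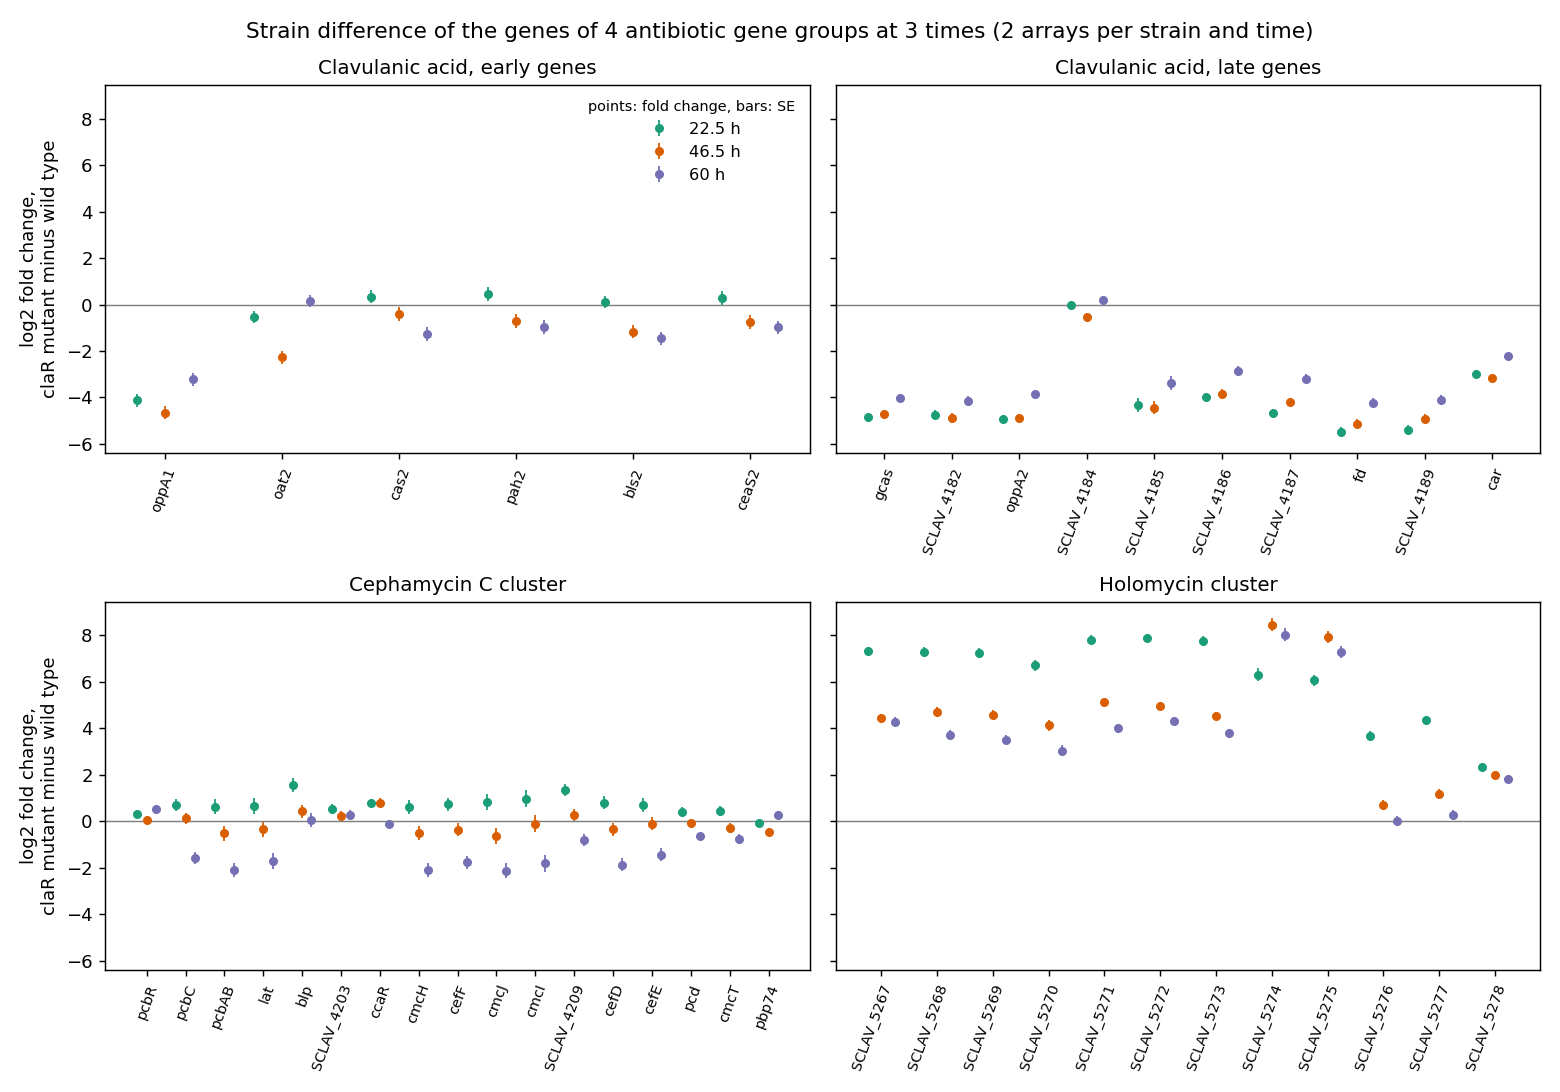
Log2 fold change of the mutant against the wild type (vertical axis) for each gene of 4 antibiotic gene groups (horizontal axis, in chromosome order) at 22.5, 46.5 and 60 h. Points are fold changes and bars their SE with 2 arrays per group, from a spread pooled over all 6 groups. At 22.5 h 9 of 10 late clavulanic acid genes lay far below 0, and all 12 holomycin genes lay above 0 at 22.5 and 46.5 h.

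At 46.5 h the late clavulanic acid genes stayed low, and 3 of 6 early genes and 7 of 14 arginine genes were lower in the mutant. All 10 late genes were lower (10 adjusted over the list alone, median -4.58), with fd at -5.12 ± 0.19 and SCLAV_4189 at -4.91 ± 0.21, and claR was at -4.35 ± 0.19. Of the early genes 3 of 6 were lower (5 adjusted over the list alone): oppA1 at -4.66 ± 0.28, oat2, an ornithine acetyltransferase gene, at -2.28 ± 0.27 and bls2, the beta-lactam synthetase gene, at -1.16 ± 0.27. All 12 holomycin genes were higher (12 adjusted over the list alone, median 4.56), with SCLAV_5274 at 8.46 ± 0.27 and SCLAV_5275 at 7.92 ± 0.25. The next highest gene was SCLAV_p1123 on pSCL4 at 6.02 ± 0.20. Camera called the late, early and holomycin lists shifted (adjusted p 1.1e-17, 0.00023 and 4e-16). None of the 3 held with an estimated correlation (adjusted p 0.11, 0.32 and 0.13).

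Arginine and urea metabolism had 7 of 14 genes lower and 1 higher at 46.5 h (7 and 1 adjusted over the list alone). They were led by arcB_1 at -4.51 ± 1.1, arlY at -2.74 ± 0.17 and argJ at -2.57 ± 0.37, and the list was called lower (adjusted p 0.00031, 0.18 with an estimated correlation). The block SCLAV_2456 to SCLAV_2469 had 13 of 14 genes lower and 1 higher, the same adjusted over the list alone, with SCLAV_2462 at -2.93 ± 0.27 and SCLAV_2463 at -2.75 ± 0.22 (adjusted p 3.2e-11, 0.18 with an estimated correlation). In the block SCLAV_4387 to SCLAV_4392 5 of 6 were lower, SCLAV_4387 first at -2.25 ± 0.33 (adjusted p 9.3e-05, 0.32 with an estimated correlation). Of 17 moe genes 7 were lower, moeH5 at -0.88 ± 0.21 (adjusted p 9.3e-05, 0.21 with an estimated correlation). Cephamycin C had only ccaR past the test, higher at 0.81 ± 0.18, and a list adjusted p of 0.40. Higher genes included trxA at 2.95 ± 0.40 and trxB at 2.39 ± 0.25 among 6 higher stress genes of 20, and acnA, for aconitase, at 1.35 ± 0.19 with icdA, for isocitrate dehydrogenase, at 1.15 ± 0.19 among 4 of 11 genes of glycolysis and the citric acid cycle. They also included trpS1 at 1.50 ± 0.18 among 3 of 22 tRNA synthetases and glpF2 at 1.57 ± 0.28 among 3 of 6 glycerol genes. Lower ones included metX at -2.65 ± 0.43 and cysE at -2.45 ± 0.20 among 3 of 14 sulfur genes. The gene cysE lies in the end of pSCL4 described above. In the clavam clusters SCLAV_p1071 was at 2.30 ± 0.25 and cvm7 at 0.92 ± 0.17.

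Over all genes 1907 changed at 46.5 h, 1135 higher and 772 lower, 533 and 509 of them 2-fold or more. On pSCL4 323 of 460 changed genes were lower (list median -0.02, adjusted p 3.8e-05, 0.47 with an estimated correlation), and the lowest of all were SCLAV_p1431 at -7.06 ± 0.55, SCLAV_p1381 at -6.97 ± 0.21 and sidD at -6.47 ± 1.34. With loess 666 genes changed, 274 higher and 392 lower, and the calls of bls2, argJ, moeH5, ccaR, trxA, trxB, icdA and trpS1 ended. The count was 967 or 1046 without either 46.5 h array of the wild type and 1140 or 981 without either of the mutant, each of which also ended the calls of arcB_1 and moeH5.

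At 60 h genes of protein synthesis and energy supply were higher in the mutant than in the wild type, and most cephamycin C genes were lower. Of 40 ribosomal protein genes 34 were higher (36 adjusted over the list alone, median 1.04), with rplW at 1.60 ± 0.17 and rplQ at 1.52 ± 0.24. Of 31 genes of oxidative phosphorylation 27 were higher and 1 lower (29 and 1 adjusted over the list alone), with qcrC at 2.29 ± 0.30 and coxa at 2.21 ± 0.30. Of 22 aminoacyl-tRNA synthetase genes 13 were higher (13 adjusted over the list alone), gltX first at 1.82 ± 0.19, and of 11 genes of glycolysis and the citric acid cycle 7 were (7 adjusted over the list alone), tpiA, for triosephosphate isomerase, at 2.75 ± 0.23 and pgk, for phosphoglycerate kinase, at 2.64 ± 0.25. Of 20 stress genes 11 were higher (12 adjusted over the list alone), with the chaperonin gene groEL2 at 1.96 ± 0.47 but -0.06 with loess. Camera called all 5 lists higher (adjusted p 1.1e-11, 7.3e-09, 1.6e-05, 0.0024 and 0.00076). The adjusted p were 0.18, 0.38, 0.25, 0.38 and 0.36 with an estimated correlation. The 2 wild-type arrays at 60 h differed in oxidative phosphorylation, with a mean centred log2 ratio of 0.21 on replicate 1 and 1.05 on replicate 2, against 2.07 and 1.77 in the mutant.

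In the cephamycin C cluster 12 of 17 genes were lower and 1 higher at 60 h, the same adjusted over the list alone. The lowest were cmcJ at -2.12 ± 0.34, pcbAB, for the synthetase that joins the 3 amino acids of the precursor, at -2.10 ± 0.32, cmcH, for a carbamoyltransferase, at -2.10 ± 0.30 and cefD, for an epimerase, at -1.87 ± 0.28. The list median was -1.44 (adjusted p 0.00049, 0.40 with an estimated correlation). Of 10 late clavulanic acid genes 9 were lower (9 adjusted over the list alone), fd at -4.22 ± 0.19 and SCLAV_4182 at -4.17 ± 0.22, and of the early genes 5 of 6 (5 adjusted over the list alone), oppA1 at -3.21 ± 0.28, bls2 at -1.45 ± 0.27 and cas2, for clavaminate synthase, at -1.28 ± 0.29. Their adjusted p were 1.5e-10 and 0.0065, and 0.18 and 0.40 with an estimated correlation. The target claR was at -3.84 ± 0.19. In the holomycin cluster 10 of 12 were higher (10 adjusted over the list alone, median 3.76, adjusted p 1.6e-11, 0.18 with an estimated correlation), SCLAV_5274 at 8.02 ± 0.27 and SCLAV_5275 at 7.28 ± 0.25. Downstream of the clavulanic acid cluster 3 of 7 genes were lower and 1 higher, SCLAV_4177 first at -1.65 ± 0.34, with a list adjusted p of 0.30.

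Smaller groups also differed at 60 h. Arginine genes were higher in 6 of 14 and lower in 1, argJ at 1.40 ± 0.37 and argB at 1.31 ± 0.30, with a list adjusted p of 0.26. Lower lists were moe with 11 of 17 genes (moeH5 at -1.19 ± 0.21), the block SCLAV_2456 to SCLAV_2469 with 6 of 14 (SCLAV_2465 at -1.23 ± 0.20) and the block SCLAV_4387 to SCLAV_4392 with 4 of 6 (SCLAV_4389 at -2.50 ± 0.20). Their adjusted p were 0.0011, 0.0057 and 0.0036, and with an estimated correlation 0.31, 0.44 and 0.40. The clavam paralogue list passed as lower with 3 of 15 genes lower and 1 higher, SCLAV_p1083 first at -2.14 ± 0.26 (adjusted p 0.038, 0.49 with an estimated correlation). The developmental regulator gene adpA was higher at 2.40 ± 0.36, and of 7 terpene genes hopE at 1.67 ± 0.34 and hopD at 1.44 ± 0.22 led 3 higher ones. Among sulfur genes cysE was at -2.54 ± 0.20, and among glycerol genes glpQ1 was at -0.92 ± 0.29. The highest genes after SCLAV_5274 and SCLAV_5275 were SCLAV_p1123 at 5.89 ± 0.20 and the neighbours SCLAV_1448 at 4.84 ± 0.30, SCLAV_1450 at 4.42 ± 0.23 and SCLAV_1447 at 4.33 ± 0.35.

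Over all genes 2617 changed at 60 h, 1500 higher and 1117 lower, 771 and 679 of them 2-fold or more. On pSCL4 406 of 501 changed genes were lower (list adjusted p 1.3e-09, 0.31 with an estimated correlation). The lowest of all were SCLAV_p1381 at -6.99 ± 0.21, SCLAV_p1410 at -6.52 ± 0.29 and SCLAV_p1389 at -6.26 ± 0.23, all in its end, and SCLAV_4939 on the chromosome at -6.23 ± 0.50. With loess 1087 genes changed, nearly as many higher as lower, and the calls of rplQ, qcrC, coxa, cas2, argB, adpA, glpQ1 and SCLAV_2465 ended. With only the 60 h arrays in the fit 1040 changed, and the calls of cas2, groEL2, argJ, glpQ1 and SCLAV_4177 ended.

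Averaged over the 3 times, the late clavulanic acid and holomycin genes differed in opposite directions. Late clavulanic acid genes were lower in 9 of 10 (9 adjusted over the list alone), fd at -4.94 ± 0.11, and early ones in 4 of 6 (6 adjusted over the list alone), oppA1 at -4.00 ± 0.16, with claR at -4.23 ± 0.11. All 12 holomycin genes were higher (12 adjusted over the list alone), SCLAV_5274 at 7.60 ± 0.16 and SCLAV_5275 at 7.09 ± 0.15, and in the end of pSCL4 SCLAV_p1381 was at -6.90 ± 0.12 and SCLAV_p1431 at -6.35 ± 0.32. Also called higher were stress proteins (8 of 20, trxA at 2.05 ± 0.23), glycolysis and the citric acid cycle (5 of 11, acnA at 1.07 ± 0.11), oxidative phosphorylation (16 of 31), tRNA synthetases (11 of 22) and ribosomal proteins (18 of 40, rpmE at 1.15 ± 0.13), whose list median of 0.30 became -0.11 with Cy3 alone. Also called lower were moe (12 of 17, moeH5 at -0.80 ± 0.12), the blocks SCLAV_2456 to SCLAV_2469 (12 of 14, SCLAV_2462 at -1.62 ± 0.16), SCLAV_4387 to SCLAV_4392 (5 of 6, SCLAV_4389 at -1.96 ± 0.11) and SCLAV_p0064 to SCLAV_p0075 (2 of 10), and pSCL4 as a whole. Of the 25 lists 13 passed at the preset correlation and 0 with an estimated one, where the smallest adjusted p were 0.12 for the late clavulanic acid and holomycin lists. Over all genes 3153 changed, 1916 higher and 1237 lower, and 628 of them 2-fold or more. The majority turned with the series matrix (1458 higher, 1724 lower) and with loess (1039 and 1110). With slide as a random block 2304 changed, and with scan date as a random block 1926 did.

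The genes called at the 3 times overlapped. Of genes higher at 22.5 h 258 were also higher at 46.5 h, where independent lists would share 55.2, and of lower genes 222 were shared against 29.3, while 3 were called in opposite directions against 80.6. Between 46.5 and 60 h 433 higher genes (226 for independent lists) and 339 lower genes (115) were shared, and 195 were called in opposite directions (322). All 3 times shared 162 higher and 171 lower genes. The 3 contrasts share each gene's variance estimate and the confounding of strain with slide and scan date. The overlaps therefore do not tell strain from batch.

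**Figure D2:**
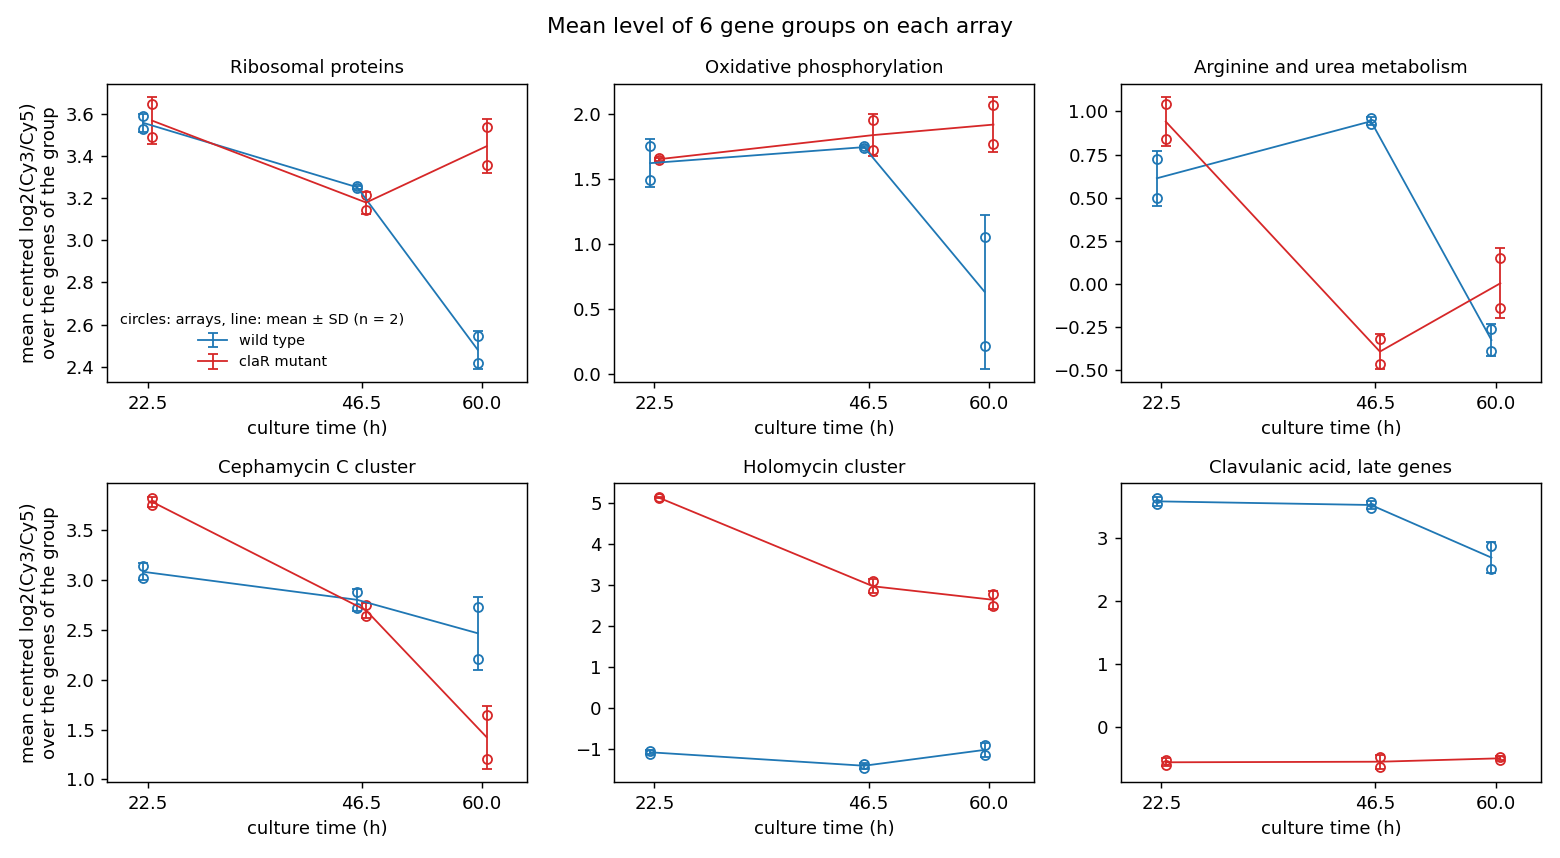
Mean centred log2 ratio over the genes of 6 groups (vertical axis) against culture time in h (horizontal axis), in the wild type and the mutant. Circles are single arrays, lines join group means and bars are the SD of 2 arrays; at 60 h oxidative phosphorylation lay at 0.21 and 1.05 on the 2 wild-type arrays and at 2.07 and 1.77 on the 2 mutant arrays.

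Of the lists not yet given, sta on pSCL4, named like a staurosporine cluster, had 1 of 15 genes higher in each strain contrast and adjusted p of 0.56, 0.49 and 0.11 at the 3 times. The clavam cluster on the chromosome had 0 of 16 genes changed at 22.5 h (limma, 0 adjusted over the list alone) and adjusted p of 0.90, 0.76 and 0.18. Of 9 phosphate supply genes 1 was higher at 46.5 h and 1 at 60 h (adjusted p 0.16 and 0.21), and of 5 nitrogen assimilation genes 2 were lower at 46.5 h and 1 at 60 h (adjusted p 0.13 and 0.49). The terpene list had adjusted p of 0.90, 0.76 and 0.23, aerial mycelium and spore genes 0.39, 0.81 and 0.72, sulfur and cysteine metabolism 0.64, 0.43 and 0.42, and glycerol uptake and use 0.72, 0.40 and 0.42. The tiled block SCLAV_p0064 to SCLAV_p0075 on pSCL4 had no changed gene of 10 at any of the 3 times (limma, no gene adjusted over the list alone) and adjusted p of 0.56, 0.14 and 0.061.

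In the wild type few genes changed between 22.5 and 46.5 h. The largest rise was in SCLAV_3996 at 2.65 ± 0.40 and the largest falls in SCLAV_1658 at -2.67 ± 0.44 and ansP at -2.51 ± 0.33. In the clavam cluster on the chromosome cvm6 at -1.99 ± 0.20 and cvm5 at -0.89 ± 0.17 fell, 2 of 16 genes (3 adjusted over the list alone, adjusted p of the list 0.040, 0.28 with an estimated correlation). The block SCLAV_2456 to SCLAV_2469 rose with 3 of 14 genes (12 adjusted over the list alone), SCLAV_2461 first at 0.92 ± 0.22 (adjusted p 8e-09, 0.28 with an estimated correlation). Phosphate supply passed as higher (adjusted p 0.011, 0.61 with an estimated correlation) with 1 of 9 genes past the test, pstA at 1.04 ± 0.26 (4 adjusted over the list alone), and moe (4 of 17 adjusted over the list alone) and SCLAV_p0064 to SCLAV_p0075 also passed as higher (adjusted p 0.00022 and 0.011, 0.28 and 0.61 with an estimated correlation). The ribosomal, tRNA synthetase, cephamycin C and holomycin lists passed as lower with adjusted p of 3.8e-05, 3.8e-05, 0.040 and 0.048, and with an estimated correlation 0.45, 0.28, 0.67 and 0.65. Within slide 1, which held both times, the ribosomal median was -0.41. The holomycin median was 0.02 there, the opposite sign to the -0.17 over all arrays, while the list mean fell from -1.13 to -1.37. Over all genes 377 changed, 119 higher and 258 lower. The count was 39 or 180 without either 46.5 h array of the wild type, 53 without replicate 2 at 22.5 h, 250 without either 46.5 h array of the mutant and 671 without either 60 h array of the wild type. It was 608 with slide as a fixed block and 22 with loess, and the calls of pstA and SCLAV_2461 ended in both. Without replicate 1 at 46.5 h the calls of SCLAV_3996, SCLAV_1658 and cvm5 ended.

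Between 46.5 and 60 h the wild type shifted broadly, with most genes of protein synthesis, respiration and clavulanic acid falling. All 10 late clavulanic acid genes fell (10 adjusted over the list alone, median -0.84), SCLAV_4185 first at -1.40 ± 0.29, and 5 of 6 early ones (5 adjusted over the list alone), oat2 at -2.08 ± 0.27. Ribosomal proteins fell in 28 of 40 (30 adjusted over the list alone, median -0.89), rplW at -1.34 ± 0.17 and rplQ at -1.30 ± 0.24, and oxidative phosphorylation in 27 of 31 with 1 rise (28 and 1 adjusted over the list alone, median -1.22), atpB at -1.77 ± 0.38 and qcrC at -1.69 ± 0.30. Arginine genes fell in 7 of 14 and rose in 1, the same adjusted over the list alone, arcB_1 at -4.51 ± 1.1 and arlY at -3.02 ± 0.17. The block SCLAV_2456 to SCLAV_2469 fell in 9 of 14 (11 adjusted over the list alone), SCLAV_2463 at -2.02 ± 0.22, and tRNA synthetases in 12 of 22 with 1 rise, trpS2 at -1.43 ± 0.25. Adjusted p of these 7 lists were 7.3e-05, 0.0083, 1.1e-10, 2.5e-09, 0.016, 5.2e-05 and 7.3e-05. With an estimated correlation they were 0.47, 0.58, 0.47, 0.47, 0.47, 0.47 and 0.47. Cephamycin C passed as lower (4 of 17, blp at -1.93 ± 0.29, adjusted p 0.045), with a median of -0.24 that was 0.10 with loess, and moe passed as lower (adjusted p 0.045). The cephamycin C list mean was 2.72 and 2.88 on the 46.5 h arrays and 2.73 and 2.21 on the 60 h arrays, so the fall lay in 60 h replicate 2. The clavam paralogue list (4 of 15, SCLAV_p1083 at 1.75 ± 0.26), sta (5 of 15, staB at 0.80 ± 0.21) and pSCL4 passed as higher (adjusted p 0.045, 0.015 and 0.015). With an estimated correlation the adjusted p of cephamycin C, the clavam paralogues, sta and pSCL4 were 0.62, and that of moe 0.59.

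The largest rises in that step were in bkdB1 at 7.96 ± 0.88 and bkdA1 at 7.93 ± 0.86, for subunits of branched-chain keto acid dehydrogenase, and in paaA, a phenylacetate degradation gene, at 6.51 ± 0.74. The highest on pSCL4 was SCLAV_p0791 at 6.07 ± 0.24, and the largest falls were in leu at -4.63 ± 0.37, arcB_1 and SCLAV_1448 at -4.49 ± 0.30. Glycerol genes rose in 4 of 6 and fell in 1, glpF2 at 1.69 ± 0.28 and glpK, for glycerol kinase, at 1.56 ± 0.22, with a list adjusted p of 0.22. Glycolysis and the citric acid cycle fell in 7 of 11 and rose in 4, pgk at -2.31 ± 0.25, tpiA at -2.14 ± 0.23 and pfkA, for phosphofructokinase, at 1.43 ± 0.22 (list adjusted p 0.079). Single falls included metX at -3.05 ± 0.43, tpx at -2.11 ± 0.33 and adpA at -2.11 ± 0.36, the last of which was 0.15 with loess. Over all genes 3022 changed, 1602 higher and 1420 lower. Within slide 3, which held both times, medians were -0.71 for ribosomal, -0.74 for oxidative phosphorylation and -1.03 for arginine genes. With loess 656 genes changed, most of them lower, and the calls of rplW, rplQ, atpB, qcrC, glpK, trpS2, tpx, blp and staB ended. The count was 1578 or 1571 without either 46.5 h array, 1985 without replicate 1 at 60 h, and 1682 with only these groups in the fit.

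In the mutant most cephamycin C and holomycin genes and 6 of 14 arginine genes fell between 22.5 and 46.5 h. Arginine genes fell in 6 of 14 (6 lower and 1 higher adjusted over the list alone), argB at -3.29 ± 0.30 and argC at -3.05 ± 0.32. Cephamycin C fell in 11 of 17 (14 adjusted over the list alone, median -1.21), blp at -1.91 ± 0.29, cmcJ at -1.73 ± 0.34 and cefD at -1.72 ± 0.28. Holomycin genes fell in 10 of 12 (10 adjusted over the list alone, median -2.81), SCLAV_5277 at -3.37 ± 0.20 and SCLAV_5273 at -3.19 ± 0.19, while SCLAV_5274 at 1.1 ± 0.27 and SCLAV_5275 at 0.85 ± 0.25, named after their values were seen, rose. Early clavulanic acid genes fell in 4 of 6 (6 adjusted over the list alone), oat2 at -1.47 ± 0.27. Phosphate supply rose in 4 of 9 (5 adjusted over the list alone), pstB at 1.67 ± 0.33, and glycerol genes in 3 of 6 (3 adjusted over the list alone), glpK at 1.83 ± 0.22. Adjusted p of these 6 lists were 0.00038, 2.7e-08, 4.4e-11, 0.00051, 0.0026 and 0.028. They were 0.32, 0.38, 0.32, 0.39, 0.55 and 0.39 with an estimated correlation. Ribosomal proteins passed as lower (8 of 40, rpsR at -0.87 ± 0.21, adjusted p 2.4e-05), but their median of -0.46 was 0.22 with loess and 0.04 with Cy3 alone. The tRNA synthetases and the block SCLAV_2456 to SCLAV_2469 also passed as lower (adjusted p 0.020 each). With an estimated correlation the adjusted p of these 3 lists were 0.39, 0.54 and 0.61.

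The largest rises in that step were in bkdB1 at 4.30 ± 0.88, bkdA1 at 4.11 ± 0.86 and SCLAV_p0713 at 4.07 ± 0.23, and the largest falls in SCLAV_p1087 at -4.08 ± 0.21 and SCLAV_p0768 at -4.01 ± 0.23. Single falls included metE_2, a methionine synthase gene, at -2.23 ± 0.36, cvmP at -2.17 ± 0.29 and ahpC, for alkyl hydroperoxide reductase, at -1.94 ± 0.23. Over all genes 1406 changed, 719 higher and 687 lower, and within slide 4, which held both times, the holomycin median was -2.96. With loess 182 changed, and the calls of argB, argC, blp, cmcJ, cefD, SCLAV_5273, SCLAV_5274, SCLAV_5275, oat2, cvmP, pstB, rpsR, metE_2 and ahpC ended. The count was 696 or 736 without either 22.5 h array of the mutant and 832 or 637 without either 46.5 h array, and 3 of these 4 ended the call of bkdA1 and 2 that of bkdB1.

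Between 46.5 and 60 h few genes of the mutant changed, and 7 of 17 cephamycin C genes fell further. The 7 genes (15 adjusted over the list alone, list median -1.37) included blp at -2.30 ± 0.29 and cefD at -1.96 ± 0.28, and the list was called lower (adjusted p 1.5e-26, 0.14 with an estimated correlation). Its median was -1.29 within slide 4 and -1.64 within slide 5. The largest falls were in SCLAV_1658 at -3.42 ± 0.44, SCLAV_0644 at -3.38 ± 0.24 and kipI at -3.26 ± 0.26, and the largest rise in SCLAV_p0833 at 3.16 ± 0.47. Early clavulanic acid (4 of 6 lower adjusted over the list alone), holomycin, moe (6 of 17 lower adjusted over the list alone) and clavam paralogue lists passed as lower (adjusted p 0.00057, 2.5e-05, 2e-05 and 0.0049). Ribosomal, arginine and nitrogen assimilation lists passed as higher (adjusted p 3e-06, 0.0025 and 0.0030). With an estimated correlation these 7 had adjusted p of 0.40, 0.38, 0.24, 0.60, 0.32, 0.28 and 0.18. Over all genes 57 changed, 11 higher and 46 lower. With loess 6 changed, with slide as a fixed block 163, and leaving out 1 array gave 10 (mutant 46.5 h replicate 2) to 127 (either 60 h array of the wild type). The calls of SCLAV_p0833, SCLAV_1658, blp and cefD ended without mutant 46.5 h replicate 2 and with loess.

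The strain difference itself changed with time in 1288 genes (F test of the interaction in limma). They included 25 of 40 ribosomal genes, 14 of 31 of oxidative phosphorylation, 8 of 11 of glycolysis and the citric acid cycle, 13 of 17 cephamycin C genes, 11 of 12 holomycin genes, 6 of 14 arginine genes, 6 of 10 late clavulanic acid genes and 9 of 14 genes of the block SCLAV_2456 to SCLAV_2469. No gene of the clavam cluster on the chromosome, sta, moe, phosphate supply, SCLAV_4387 to SCLAV_4392 or SCLAV_p0064 to SCLAV_p0075 was among them. The arginine gene arlY had an adjusted p of 6.21e-05, lower in the mutant at 46.5 h (-2.74) and higher at 60 h (1.08). With loess 100 genes passed. The count was 713 without mutant 60 h replicate 1, 734 or 834 without either 46.5 h array of the wild type, 750 without mutant 46.5 h replicate 2 and 2287 without wild-type 60 h replicate 2.

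**Figure D3:**
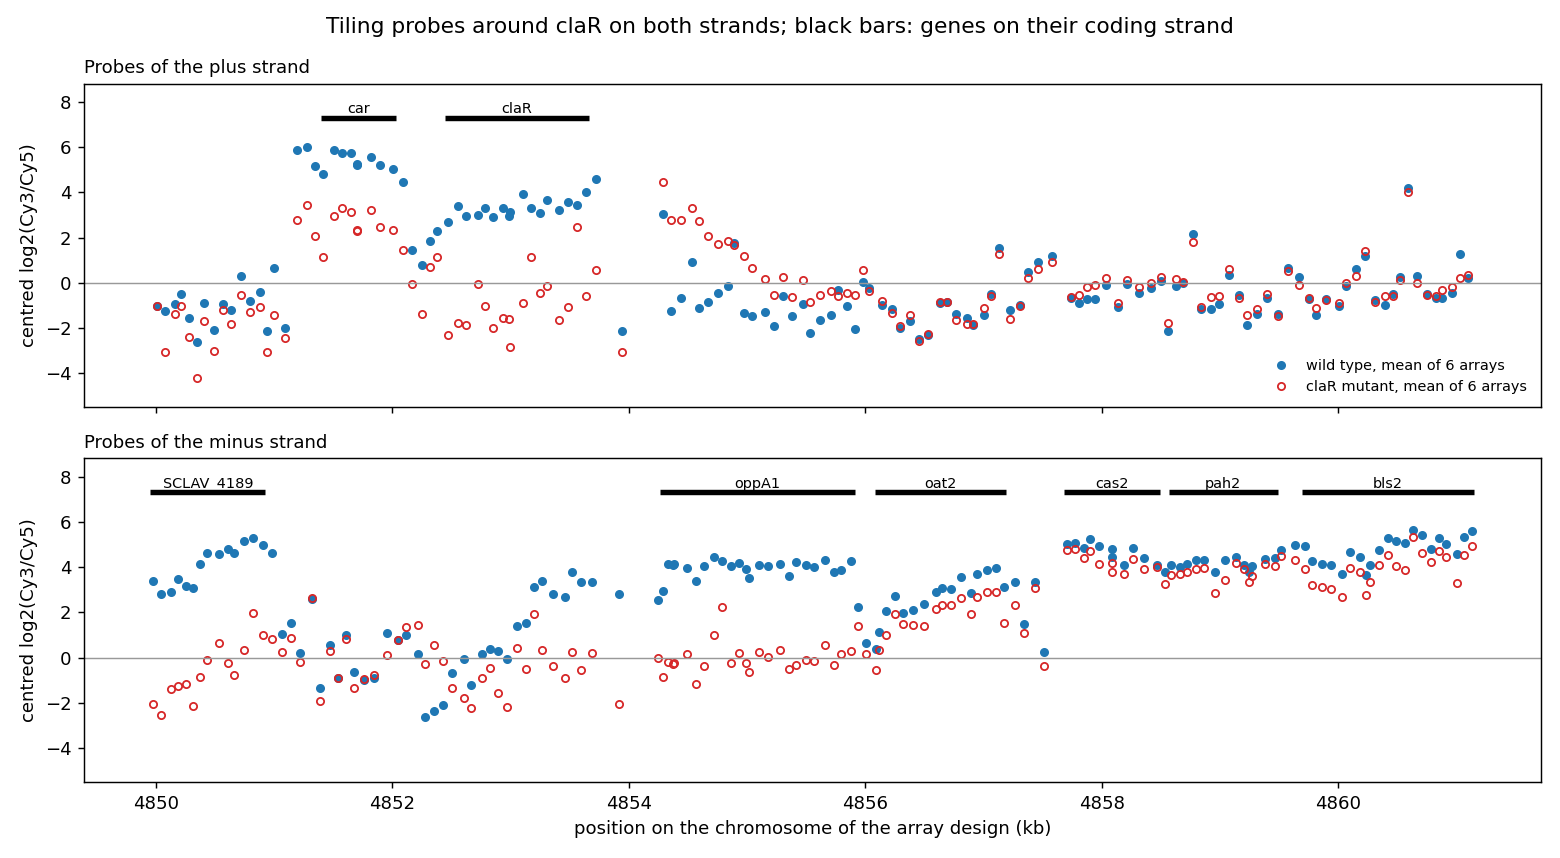
Centred log2 ratio of tiling probes around claR (vertical axis) against their position in kb on the chromosome of the array design (horizontal axis), on the plus and the minus strand, as means over the 6 arrays of each strain. The 17 sense probes of claR had a median of 3.30 in the wild type and -1.06 in the mutant.

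The end of pSCL4 differed from the rest of the megaplasmid in every strain contrast. From SCLAV_p1323 at position 1490439 to the last gene at 1796166, 269 genes had a median strain difference of -0.74 at 22.5 h, -0.84 at 46.5 h and -0.97 at 60 h. Averaged over the times 177 of them were lower and 5 higher, with a median of -0.88 against -0.05 for the 1340 genes before them. This stretch was delimited after its values were seen. The 1340 genes before the stretch had medians of 0.04 at 46.5 h and -0.23 at 60 h. With the stretch left out, the 1314 of them without missing values ranked lower than other genes. Their unadjusted camera p were 0.00778 and 2.13e-06, and 0.342 and 0.116 with an estimated correlation.

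**Figure D4:**
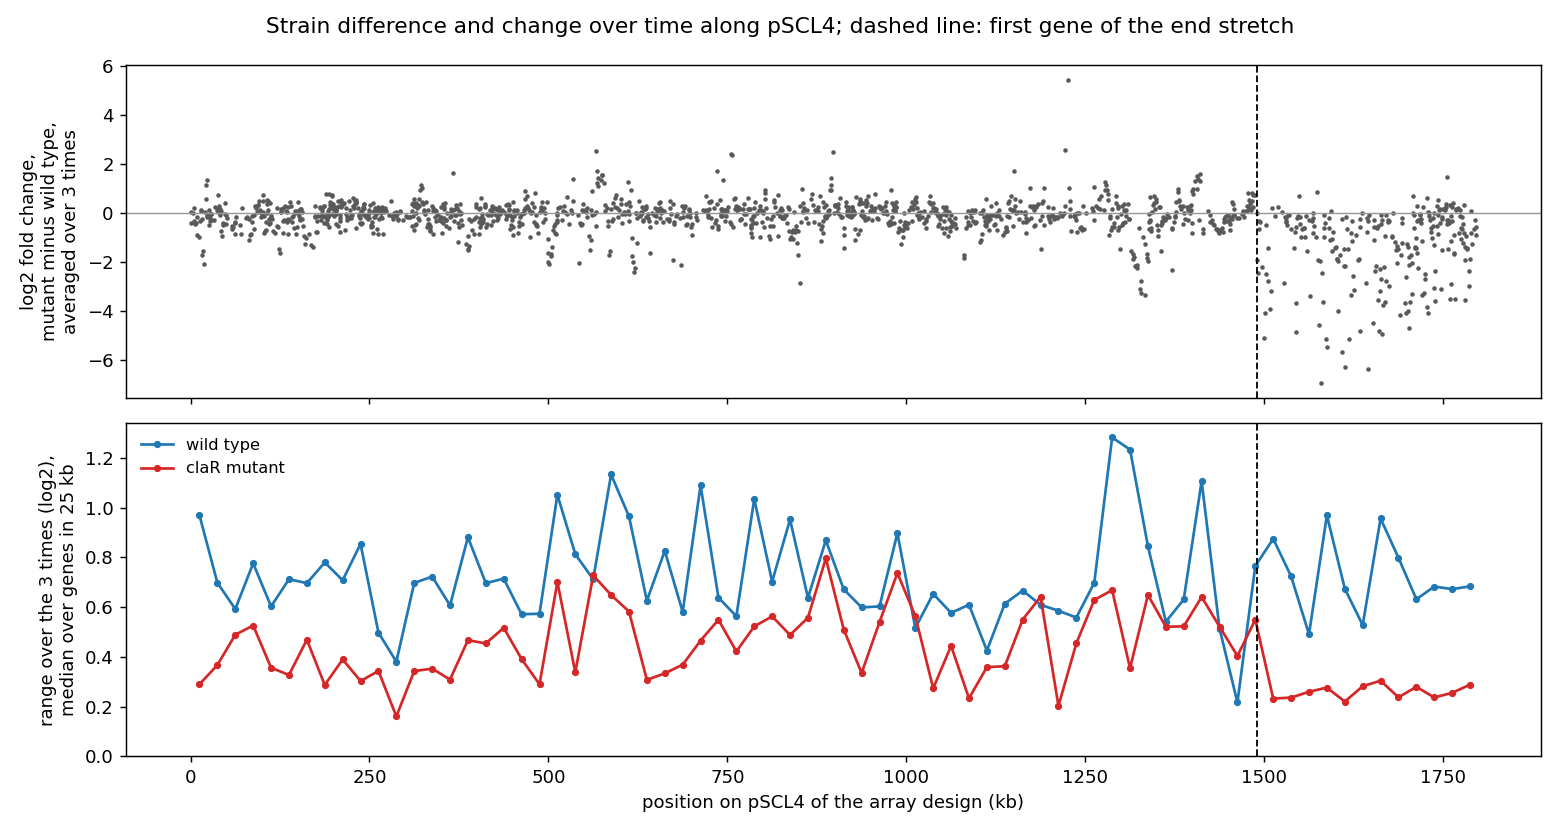
Averaged log2 fold change of each gene (upper panel) and the median range over the 3 times for genes in windows of 25 kb (lower panel) against position on pSCL4 in kb, with a dashed line at the first gene of the end. In the end the median range over time was 0.244 in the mutant and 0.715 in the wild type.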

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

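The tests on the genomic DNA channel, the slides and the antisense signal were chosen after the results were seen, and the counts of other splits were planned before.

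The F test of strain by time found 1288 genes whose time course differed between strains. By that test the time course of arlY (adjusted p 6.21e-05) differed, with strain differences of 0.56, -2.74 and 1.08 at 22.5, 46.5 and 60 h. That of SCLAV_p0791 (6.21e-05) had differences of -0.51, 1.52 and -4.23. The neighbours on pSCL4 SCLAV_p0015 (6.21e-05; 0.01, -0.42, -4.69), SCLAV_p0016 (6.21e-05; 0.05, -0.22, -4.45) and SCLAV_p0017 (6.21e-05; -0.16, -0.94, -5.12) differed almost wholly at 60 h. The holomycin genes SCLAV_5272 (6.21e-05; 7.91, 4.98, 4.33), SCLAV_5273 (6.83e-05; 7.77, 4.53, 3.79) and SCLAV_5277 (8.27e-05; 4.34, 1.17, 0.28) differed most at 22.5 h. SCLAV_5020 (8.27e-05) had differences of 0.22, 1.61 and -1.62, and SCLAV_1450 (8.49e-05) of -0.02, 0.57 and 4.42.

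Among the 3249 probes not named after a gene, which entered no comparison of genes, limma called 665 changed at 22.5 h (568 higher, 97 lower), 321 at 46.5 h (191 and 130), 376 at 60 h (122 and 254) and 741 averaged over the times (436 and 305). Across 139 genes with 5 or more antisense probes, averaged antisense and sense changes correlated with r of 0.688. The counts therefore do not separate antisense transcripts from signal that follows the sense strand.

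Of the 22 antisense probes over oppA1, at 4854260 to 4855943 on the chromosome beside claR, 20 were higher in the mutant and 0 lower averaged over the times (limma), with medians of 1.71, 1.20 and 1.45 at the 3 times. Reading of the sense transcript by antisense probes was excluded by the 24 sense probes of oppA1, which had a median change of -4.11. A rise of all antisense signal on the mutant arrays was excluded as the whole cause by the 2348 antisense probes of other genes, with a median of 0.0295 averaged and 0.25, 0.15 and -0.34 at the 3 times, though 439 of them were higher and 47 lower at 22.5 h. A candidate explanation is transcription running out of aac, the resistance gene put in place of claR. The rise over oppA1 fell with distance from claR (Spearman rho -0.697, permutation p 0.00042 over 22 neighbouring probes, which are not independent). But the 2 plus-strand probes between claR and oppA1, which such a transcript would cross, were lower by -4.02 and -0.88 (median -2.45), and 4 minus-strand probes at 4852191 to 4852447, before claR, were higher by 1.28 to 2.92, so it stays open, because the extent of the replaced DNA is not given, as does an untested effect of the missing ClaR protein.

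Averaged over the times 3153 genes and 13 lists (0 in camera with an estimated correlation) differed between strains, while strain was confounded with slide and scan date. Of 100 drawn from the 108 splits of the arrays within times, 1, the real one, gave 3153 genes. The highest other gave 1751, with strains kept at 2 times and turned at 1, and another split of that kind gave 1158. Most other splits mixed the strains within a group, which raises the spread within groups and so lowers the count. For the genes the splits therefore cannot decide whether chance gave the number. For the number of lists chance was not excluded, since 7 splits gave 13 or more and the highest other gave 17. For the 628 genes changed 2-fold or more the median absolute difference was 1.44 in the ratio and 0.154 in the genomic DNA channel. A hybridisation or scan batch that moved the genomic DNA channel by as much as the ratio was thus not seen over these genes as a set. A batch that moved both channels alike would cancel in the ratio. One that moved mainly Cy3 would not show in the genomic DNA channel, so it stays open. A batch of culture, RNA or labelling in the cDNA channel alone cannot be told apart from strain, as 0 slides held both strains. This holds for the 628 genes as for the 2525 changed less than 2-fold. The genomic DNA channel alone, in which every array held wild-type DNA, gave 1078 changed genes in limma (r with the ratio -0.0828 across genes). Of these 475 were also changed in the ratio.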

How the results depend on the processing

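Alternatives added after the data were seen are centring on all non-control probes, scan date as a block, the average without 60 h, the genes without the end of pSCL4, and lists with slide as a block. Within-array loess gave 666 genes at 46.5 h (274 higher, 392 lower; 1907 reported), 1087 at 60 h (541 and 546; 2617), 22 in the first wild-type step (12 and 10; 377), 656 in the second (249 and 407; 3022), 182 in the first mutant step (110 and 72; 1406), 6 in the second (2 and 4; 57), 100 in the interaction (1288) and 51 shifted lists (80). With an estimated correlation 2 lists passed, and with slide as a block 62. With slide as a block 8 passed on average (13 reported), 4 in the first wild-type step (9) and 7 in the second (12). In the second mutant step 9 did (8). Loess also reversed ccaR (-0.26; 0.79), trxA (-0.024; 2.25) and trxB (-0.23; 2.11) at 22.5 h, groEL2 at 60 h (-0.058; 1.96) and adpA in the second wild-type step (0.15; -2.11). The series matrix gave 90 in the second mutant step, and slide as a fixed block 608 in the first wild-type step and 163 in the second mutant step. With only the 2 groups compared, which leaves 2 residual degrees of freedom, 2919 genes changed at 46.5 h, 1040 at 60 h and 1682 in the second wild-type step, and this setting cannot apply to the average or the interaction. Scan date as a random block gave 1926 on average. The causes of these shifts were not tested.

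The share of higher genes moved by more than 10 points at similar counts in these settings: at 22.5 h (366 higher, 286 lower) with loess 145 and 350, Cy3 alone 255 and 462, the series matrix 376 and 479, centring on all probes 222 and 315, and without the end of pSCL4 345 and 157; at 46.5 h (1135, 772) with the matrix 910 and 1195; at 60 h (1500, 1117) with centring on all probes 1866 and 794; on average (1916, 1237) with loess 1039 and 1110 and the matrix 1458 and 1724; and in the first mutant step (719, 687) with Cy3 alone 984 and 560. The median of all genes shifted by -0.15, -0.16, -0.18 and -0.10 in the second wild-type step with loess, Cy3 alone, the matrix and centring on all probes. At 22.5 h it shifted by -0.15, -0.10 and -0.11 with the last 3, at 60 h by 0.12 with Cy3 alone and 0.19 with centring on all probes, and with the matrix by -0.16 at 46.5 h and -0.11 on average.

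Leaving out 1 array assumes that the lone array left in a group varies like the other groups. Counts ranged from 321 (without mutant 22.5 h replicate 1) to 1018 (either wild-type 60 h array) at 22.5 h, where the other 22.5 h arrays gave 377, 344 and 325. At 46.5 h they ranged from 967 to 2433, with 967, 1046, 1140 and 981 without each 46.5 h array, at 60 h from 1755 to 2924 and on average from 2477 to 3402. The first wild-type step ranged from 39 (without wild-type 46.5 h replicate 1) to 671 (either wild-type 60 h array), with 180, 53 and 250 as in the report. The second ranged from 1571 to 3529, with 1578 and 1571 without either 46.5 h array and 1985 without 60 h replicate 1. The first mutant step ranged from 637 to 1819, with 696, 736, 832 and 637 without each array compared. The second ranged from 10 (mutant 46.5 h replicate 2) to 127 (either wild-type 60 h array), with 29 without mutant 46.5 h replicate 1, 25 and 105 without the 60 h arrays and 37 without either 22.5 h array. The interaction ranged from 713 (mutant 60 h replicate 1) to 2287 (wild-type 60 h replicate 2), with 734 and 834 without the wild-type and 750 without the second mutant 46.5 h array.

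Replicate numbers share only a label, and no pairing of cultures is given. With a replicate block 682, 1874, 2617 and 3104 genes changed between strains, 394, 2949, 1393 and 74 in the time steps and 1254 in the interaction, and with the block within strain 345, 2769, 1279 and 68 in the time steps. Deviations of replicate 1 correlated between -0.197 and 0.361 over 15 pairs of groups. For 101 named genes with 164 values, 3986 alternative values were computed. Of these 3803 kept their side of the test, 178 lost a call, 5 reversed and 0 gained one. Genes were named mainly because they were called, so few could gain a call. The 3986 also include fits that left out an array of neither group compared, so the share kept does not measure stability. Loess alone ended the calls of 54 of the 164 values and reversed 5.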

Other observations

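The stretch at the end of pSCL4 was delimited, and its tests chosen, after the values were seen.

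In the mutant the last 305.7 kb of pSCL4, from SCLAV_p1323 to position 1796166, gave low and flat signal. Its 269 genes had a median range over the 3 times of 0.244 in the mutant and 0.715 in the wild type. The 1340 genes before it had 0.426 and 0.695, and the lowest mutant median of a run of as many genes elsewhere was 0.318. Because the stretch was delimited after the values were seen, these ranges describe it and do not test whether it is flatter than the rest. A difference in the genomic DNA channel of these probes was excluded, with a median strain difference of 0.017. DNA of this stretch missing from the mutant culture and silent transcription with the DNA present cannot be told apart, because 0 arrays measured DNA of the mutant. In the mutant 6 of the genes stayed above 1, which does not show that their DNA was present. The highest of the 17 sense probes of claR, the gene replaced in the mutant, also read 2.49 in the mutant (median of the 17 -1.06). The extent of the replaced DNA is not given, so that probe may lie on DNA that was kept. Of 32 genes of the stretch above 1 in the wild type, 27 were lower in the mutant averaged over the times and 8 were within 1 of the wild type, counts that overlap.

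Tiling probes in that stretch, at 1723658 to 1725220, gave on the plus strand a median of -0.38 in the wild type and -3.20 in the mutant, with 19 of 21 probes lower by 1 or more. On the minus strand the medians were -2.27 and -2.47, with 0 of 20 lower by 1.

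The step of the mutant from 22.5 to 46.5 h shared genes with both steps of the wild type. Of 719 genes that rose in it 447 rose in the wild type from 46.5 to 60 h, where independent lists would share 153, and 26 fell. Of 687 that fell 374 also fell, against 130, and 30 rose. Across genes r was 0.549, against 0.463 with the wild-type step over the same hours, where 47 rising genes (11.4 for independent lists) and 211 falling genes (23.5) were shared. The lists differ in length, so the overlaps do not rank the 2 steps. No array is shared between the strains, but the steps share each gene's variance estimate. With loess 178 of the 1406 calls of the mutant step and 579 of the 3022 calls of the wild-type step from 46.5 to 60 h were kept. The overlaps are those without loess, and a test of a shift in time was not run.

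The gene bkdB1 is given because it had the largest rise in both of those steps. In the mutant bkdB1 rose by 4.30 ± 0.88 from 22.5 to 46.5 h, a call lost without replicate 2 of either time, and in the wild type by 7.96 ± 0.88 from 46.5 to 60 h. Between strains bkdB1 was at -0.14 at 22.5 h, 4.50 at 46.5 h and -4.98 at 60 h.

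Of 139 genes with 5 or more antisense probes 1, oppA1, had antisense and sense medians of 1 or more in opposite directions.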
